A study of Mus musculus with 8 samples.

How the data were processed

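Total RNA from FACS-sorted Purkinje cells and ventricular myocytes of 4 adult male mouse hearts was extracted with a PicoPure kit and amplified with a Nugen Ovation Pico WTA kit before hybridization to Affymetrix mouse arrays, per the labels. The deposited values are array intensity signals on a linear scale made with MAS5, per the submitters' processing notes, which give no version. The intensity values that the authors deposited were scaled so that the trimmed mean of each of the 8 arrays is 150.001, as the values show. The authors' deposited table also gives a ratio of the 2 group means and an unadjusted p-value per probe set. That p-value matched a two-sided paired test of the linear signals, with same-numbered arrays paired, to within 5e-10 in every probe set. The array columns of both deposited tables were identical in all 45101 probe sets, and no pair of arrays was identical.

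Probe sets were named through the platform annotation: 34958 had 1 gene symbol, 932 had several and 9211 had none, and symbols updated through gene identifiers to the GRCm38.p6 annotation changed in 0 cases. Probe sets naming several genes or none were not named here, and 64 control probe sets were left out. No probe set used here named 4 of the 17 genes of the fixed panel alone, and these and some list members are not reported here. Each of 18193 genes was represented by the probe set with the highest mean log2 signal over all 8 arrays. Genes were tested where that mean was above the 40th percentile of all probe sets (log2 4.31, a signal of 19.9), which left 12318. Signals were taken to log2 with no further normalization; 10 values of 0 were set to 0.1, none of them in a tested gene. Fold changes of genes with ventricular signals near that limit are uncertain: with 16 added before log2, that of Cntn2 is 26.4-fold and that of Pcp4 40.0-fold.

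Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), two-sided, without a heart block, with Benjamini-Hochberg adjustment at 0.05. Gene lists (35, of which 33 had at least 3 tested genes) were tested with camera at a preset correlation of 0.01 on the same values, adjusted over lists, with camera at an estimated correlation and fry beside it. Of 33 lists camera called 20, of which 13 were higher and 7 lower; none of the 20 held with an estimated correlation, and fry, which does not compare a list with other genes, called 22. The lists share 54 genes. Median and camera direction differed in sign in 1 list, the potassium channels. The design, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes are the panel (Cntn2, Pcp4, Gja5, Gja1, Irx3, Tbx3, Tbx5, Nkx2-5, Myh6, Myl2, Cacna1g, Ryr2, Kcnj2 and the 4 not reported), the 10 largest increases and 10 largest decreases among called genes with no overlap between groups and an established name, and up to 4 called members of each list with the largest change, or up to 2 members where none was called.

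Replicate numbers pair the arrays: the series design names 4 hearts and the authors' deposited p-value pairs same-numbered arrays. Deviations from the group means correlated between same-numbered arrays at 0.38, 0.23, 0.27 and 0.27 over genes, and each of the 4 Purkinje and 4 ventricular arrays matched its own number best. Some margins were narrow. Between other numbers within hearts 1 and 2 or within hearts 3 and 4 the correlations were 0.09 to 0.225. Across these pairs of hearts they were -0.30 to -0.14. The fit with the heart as a block is given beside a result where it changes a call or moves a count by over 1.5 times.

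The test was checked on simulated data with the means and spreads of the 12318 genes and 200 changed genes: 38 of 100 genes changed 2-fold and 78 of 100 changed 4-fold were recovered, with 4 other genes called. Simulated genes were drawn independently and without a heart effect, unlike the real arrays, so the 4 gives no error rate for these data. Alternatives were the heart block, quantile normalization and median centring, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, every probe set, 16 or 64 added before log2, other variance models, array weights, an unequal-variance test per gene, and leaving out each array or heart. Those added after seeing the data were a floor of 32, the pair of hearts as a term, each pair of hearts alone, the block with that floor, with quantile normalization or without heart 1, Cntn2 left out, and the authors' paired test.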

Results

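The series compared cardiac Purkinje cells, the myocytes of the distal conduction system, with ventricular working myocytes from adult male mice. Both cell types were sorted by FACS after enzymatic digestion of perfused hearts from animals carrying a Cntn2-EGFP reporter and an a-MHC-Cre driven tdTomato reporter. There were 4 Purkinje and 4 ventricular arrays, 1 of each per heart, from 4 separate hearts on a mixed strain background. The question was which genes distinguish Purkinje cells from ventricular myocytes. Each array had been scaled to the same trimmed mean signal of 150.001, while its median signal lay between 36.1 and 42.9 on the Purkinje arrays and between 28.2 and 32.3 on the ventricular arrays. With 4 arrays per group, the number of arrays limits the precision of every value.

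Genes of the conduction system and of neural adhesion and guidance were among those that differed most. The 10 largest increases among genes with no overlap between groups were Cntn2, Pcp4, Drd2, Slit3, Pvalb, Slit2, Fgf12, Gja5, Olfm1 and Slc16a12. Cntn2, a neural cell adhesion molecule whose reporter the sorted cells carried and which is therefore no independent finding, had a signal of 866 ± 473 (SD, n = 4) in Purkinje arrays and 12.98 ± 8.66 in ventricular arrays. Pcp4, a calmodulin-binding peptide, reached 2226 ± 1431 against 30.5 ± 12.6, a log2 fold change of 5.98 ± 0.52 (SE; limma adjusted p = 0.000952). Gja5, which encodes connexin 40, was at 818 ± 436 against 34.7 ± 10.8, with a log2 fold change of 4.40 ± 0.44. The dopamine receptor gene Drd2 (log2 fold change 5.63), the guidance ligand genes Slit3 (5.05) and Slit2 (4.68), and Pvalb, which encodes the calcium buffer parvalbumin (4.93), were also raised in 4 of 4 hearts. Ventricular means of Drd2 (12.6), Slit3 (7.05) and Pvalb (4.53) lay under a signal of 19.9, the limit for testing, so the order of the largest increases is uncertain. With 16 added before log2 all 4 still passed, Drd2 at 21.9-fold, Slit2 at 15.2-fold, Slit3 at 7.5-fold and Pvalb at 7.15-fold.

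The largest decreases were smaller. They were in Meig1 (log2 fold change -2.21), Lrtm1 (-2.08), Il13ra1 (-1.63), Scn4b (-1.60), Gpt (-1.57), Gsdme (-1.54), Cavin4 (-1.50), Slc25a13 (-1.46), Cyfip2 (-1.40) and Mpp6 (-1.37). Other probe sets above the signal limit gave decreases as small as -0.50 for Il13ra1, -0.48 for Cyfip2 and -0.59 for Mpp6. For Lrtm1 another gave -1.83 and for Gpt -2.14. Scn4b, a sodium channel beta subunit, fell from 1099 ± 221 in ventricular to 412 ± 230 in Purkinje arrays (adjusted p = 0.0453). Gpt, an alanine aminotransferase, was at 133 ± 31.9 in Purkinje and 392 ± 84.9 in ventricular arrays (adjusted p = 0.0108). Meig1 averaged 16.1 on the Purkinje arrays, under the limit of 19.9, and was 2.58-fold lower with 16 added. All 10 were lower in 4 of 4 hearts, and each named gene that passed moved the same way in 4 of 4 hearts.

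**Figure D1:**
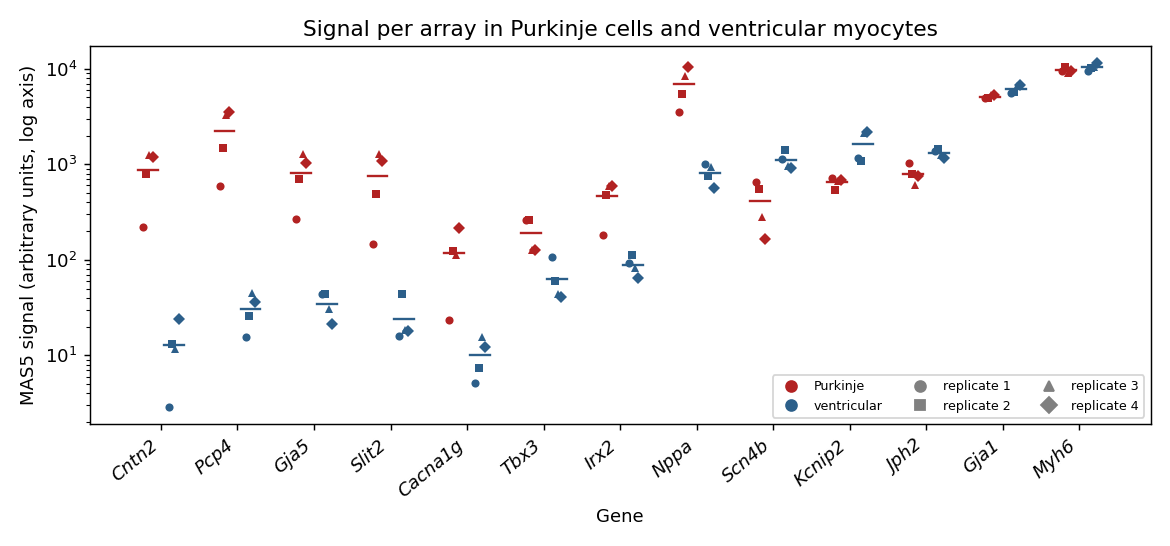
MAS5 signal (log axis) of 13 genes on each array, Purkinje in red and ventricular in blue; marker shapes give the replicate number, which is the heart, and bars the mean of 4 arrays. Pcp4 and Gja5 lie above all ventricular arrays on every Purkinje array, Purkinje replicate 1 is lowest for Cntn2, Pcp4 and Gja5, and Myh6 overlaps between groups.

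Of 12318 genes tested with limma, 365 passed an adjusted p of 0.05, 239 higher and 126 lower in Purkinje cells, and 235 of them differed at least 2-fold. Camera at its preset correlation called 20 of 33 gene lists. It called as many as 17 on other splits of the 8 arrays on which no gene passed. The split with 17 kept Purkinje replicates 1, 2 and 3 on 1 side, so it held part of the real contrast. On splits with 2 arrays of each cell type per side it called up to 9. None of the 20 held with an estimated correlation. In 355 of the 365 the groups did not overlap; over all tested genes this held for 12.7%, where chance gives 2.86%. With the heart as a block, 2108 genes passed (1187 higher, 921 lower), among them all 365. With each pair of hearts tested alone, 3 genes (Acta2, Nppa and Pcp4, named after their values were seen) passed within hearts 1 and 2, and 1579 within hearts 3 and 4. The count was 957 without ventricular replicate 1, 123, 38 and 165 without Purkinje replicate 2, 3 or 4, and 101, 69 and 67 without ventricular replicate 2, 3 or 4. Without Purkinje replicate 1 it was 535, with 233 lower. All counts given here with 1 array left out come from fits without the heart block, in which the pairing is not used. In the 1 blocked fit with a heart left out (heart 1, chosen after seeing the data) 2415 genes passed, among them all 365. Heart 1 holds the Purkinje array nearest the ventricular ones, and without it the count also rose in the fit without the block, to 857. Without heart 2, 3 or 4 that fit gave 10, 6 and 9 genes. No blocked fit was run without those hearts, so the 2415 does not show that the calls hold without any 1 heart. After quantile normalization 122 genes were higher and 40 lower (75.3% higher, against 65.5%), and after median centring 222 were higher and 2385 lower (8.52% higher). The median log2 fold change of all tested genes was 0.05, -0.06 after quantile normalization and -0.35 after median centring.

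Of 16 tested conduction system markers, 11 were higher in Purkinje cells, none was lower and 5 did not pass (13 higher when adjusted over the list alone, camera adjusted p = 1.29e-13, and adjusted p = 0.145 with an estimated correlation). With Cntn2 left out 10 of 15 were higher (11 adjusted over the list alone, camera adjusted p = 2.59e-12, and adjusted p = 0.144 with an estimated correlation). Besides Cntn2, Pcp4, Slit2 and Gja5 they included the transcription factor genes Tbx3 (log2 fold change 1.64 ± 0.37, adjusted p = 0.0406) and Tbx5 (1.44 ± 0.33, adjusted p = 0.0439). Irx3 (0.36, adjusted p = 0.204) and Nkx2-5 (0.42, adjusted p = 0.329) did not pass. Of 8 sinoatrial node factors, Tbx3 and Cacna1g were higher (3 higher adjusted over the list alone and 3 with the block, camera adjusted p = 0.00630, and adjusted p = 0.145 with an estimated correlation). The conduction list averaged 0.30 above its 8-array mean on Purkinje replicate 1 and 1.31 to 1.64 on the other Purkinje arrays (log2). The 11 fell to 5 without Purkinje replicate 2, 3 or 4 or ventricular replicate 2 or 4, and to 6 without ventricular replicate 3. Neither sinoatrial gene passed without any 1 of these 6 arrays.

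In the neural adhesion and axon guidance list 12 of 35 genes were higher and none lower (16 higher and 2 lower adjusted over the list alone, 18 higher and 2 lower with the block). Besides Cntn2 they were led by Slit3, Slit2 and Sema3a, a secreted semaphorin at 689 ± 542 in Purkinje and 29.4 ± 7.37 in ventricular arrays. For this list camera gave an adjusted p of 1.36e-07, and adjusted p = 0.145 with an estimated correlation. With Cntn2 left out 11 of 34 were higher (15 and 2 adjusted over the list alone, camera adjusted p = 9.44e-07, and adjusted p = 0.144 with an estimated correlation). Without Purkinje replicate 3, ventricular replicate 2, 4 or 3 the 12 became 5, 7, 6 and 8, in that order, and 1 gene was lower without Purkinje replicate 1. Among 34 cardiac transcription factors, Irx2, Irx1, Tbx3, Irx5 and Tbx5 were higher and none was lower (8 higher and 3 lower adjusted over the list alone, 9 higher and 5 lower with the block). That list was not called by camera (adjusted p = 0.252, and 0.0375 after quantile normalization), and its median of 0.12 was -0.28 after median centring. Without Purkinje replicate 2, 3 or 4 and ventricular replicate 2, 3 or 4 the higher genes numbered 2, 1, 2, 3, 2 and 2, and without Purkinje replicate 1 there were 4 higher and 3 lower. Of 19 Notch pathway genes, Mfng and Heyl were higher (8 adjusted over the list alone, 11 with the block). Its camera adjusted p was 2.07e-05, with adjusted p = 0.285 with an estimated correlation. Relative to its 8-array mean the Notch list averaged 0.92, 0.63, 0.15 and -0.07 on Purkinje replicates 1 to 4 and 0.23, -0.42, -0.69 and -0.75 on the ventricular ones (log2). On the same arrays the endothelial marker list averaged 1.25, 0.99, 0.30 and -0.25 and at 0.50, -0.72, -1.12 and -0.96, and the smooth muscle and pericyte list 1.10, 0.91, 0.12 and 0.14 and at 0.02, -0.52, -0.82 and -0.95. Of the Notch list's members 7 were higher without ventricular replicate 1, 1 without Purkinje replicate 4 and 0 without any other single array (1 lower without Purkinje replicate 1), where limma at an unadjusted p under 0.05 called between 2045 and 2718 genes of all tested.

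Ion channel genes moved both ways. Of 13 calcium channel genes 3 were higher and 1 lower (3 and 2 adjusted over the list alone and with the block): the T-type genes Cacna1h (log2 fold change 3.87 ± 0.64) and Cacna1g (3.32 ± 0.64) and the auxiliary subunit gene Cacna2d2 (2.40 ± 0.53) rose, and Cacna1c, the L-type pore subunit, fell by 0.59 on the log2 scale. Cacna1g averaged 10.1 on the ventricular arrays and Cacna1h was at 4.40 on ventricular replicate 1, under the limit of 19.9; with 16 added they were 4.39-fold and 7.59-fold higher. Of 9 sodium channel genes and partners, Fgf12 (4.47 ± 0.59; 11.6-fold with 16 added) and Scn10a, which encodes Nav1.8 (2.52 ± 0.37), were higher and Scn4b lower (3 and 2 adjusted over the list alone, 4 and 2 with the block). Of 32 potassium channel genes Kcnj8 (1.29 ± 0.28), also a member of the smooth muscle and pericyte list, was higher and Kcnip2 (-1.27 ± 0.23) lower (2 and 3 adjusted over the list alone, 7 and 4 with the block), and Kcnj2 gave -0.27 (adjusted p = 0.617). None of these 3 lists was called by camera (adjusted p = 0.557, 0.209 and 0.862); the list of sodium channels was called after median centring (0.0227) and with every probe set (0.0468). Without Purkinje replicate 3 none of the higher calcium channel genes passed, and without Purkinje replicate 2 or 4 or ventricular replicate 2, 3 or 4 there was 1. Cacna1c passed without ventricular replicate 1 but not without any other single array. Higher and lower potassium channel genes numbered 0 and 3 without Purkinje replicate 1, 3 and 2 without ventricular replicate 1, 0 and 1 without ventricular replicate 2, and 0 and 0 without Purkinje replicate 2 or 3 or ventricular replicate 3 or 4. Scn4b passed without Purkinje replicate 1 or ventricular replicate 1 but not without any other single array. The median of the calcium channel list was 0.11, -0.24 after quantile normalization and -0.29 after median centring. Of 10 pacemaker, chloride and cation channel genes none passed (adjusted over the list alone also 0; 1 higher and 1 lower with the block), with Ano1 at a log2 fold change of 1.33 (adjusted p = 0.0832, 0.0134 with the block) and Trpv2 at 0.62.

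Of 20 connexin and junction genes Gja5 and Gjc1, which encodes connexin 45 (1.43 ± 0.20), were higher and none lower (2 and 0 adjusted over the list alone, 4 and 4 with the block, camera adjusted p = 0.485, and 0.00693 after quantile normalization). Gja1, the main ventricular connexin gene, was at 5115 ± 201 in Purkinje and 6131 ± 587 in ventricular arrays (adjusted p = 0.140, 0.0459 with the block). Of 29 calcium handling genes Pcp4, Pvalb and the phosphatase inhibitor gene Ppp1r1a were higher and Jph2 lower (3 and 3 adjusted over the list alone, 6 and 5 with the block, camera adjusted p = 0.918), and Ryr2 gave -0.15 (adjusted p = 0.588). Jph2 passed without Purkinje replicate 1 or ventricular replicate 1 but not without any other single array. In the T-tubule and dyad list Jph2, which encodes junctophilin-2 (-0.73 ± 0.17), and Cacna1c were lower among 14 genes (0 and 3 adjusted over the list alone, 1 higher and 4 lower with the block). Camera gave this list an adjusted p of 0.00925, with adjusted p = 0.152 with an estimated correlation, and 0.290 after quantile normalization. Its lower genes numbered 2 without ventricular replicate 1, 1 without Purkinje replicate 1 and 0 without any other single array.

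No sarcomere gene of 40 passed over all genes (2 higher and 3 lower adjusted over the list alone, 4 higher and 7 lower with the block). Myh6 (-0.10, adjusted p = 0.546) and Myl2 (-0.05, adjusted p = 0.784) did not pass. The list median was -0.14 and its mean 0.04. Without Purkinje replicate 1 there were 2 higher and 1 lower. Leaving out ventricular replicate 1 gave 2 lower, and Purkinje replicate 4 or ventricular replicate 2 gave 1 higher; within hearts 3 and 4 alone 5 were higher and 20 lower. Camera called it lower with an adjusted p of 0.00223, with adjusted p = 0.352 with an estimated correlation, and the direction turned after quantile normalization (0.942). Its largest values were in the atrial light chain genes Myl7 (4.43, adjusted p = 0.227, 0.000739 with the block; 21.5-fold, and 10.3-fold with 16 added, with signals under 19.9 on 3 arrays) and Myl4 (3.72, adjusted p = 0.0505, 8.68e-05 with the block).

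Of 29 fatty acid oxidation genes 6 were lower, 23 did not pass and none was higher, with a median of -0.38 (16 lower adjusted over the list alone, 18 with the block). They included Cpt2, which acts in mitochondrial import of fatty acids (1088 ± 96.8 against 1807 ± 213), Eci2 (-0.70 ± 0.15), Eci1 (-0.68 ± 0.13) and Slc25a20 (-0.57 ± 0.12); another probe set of Cpt2 gave 0.37. Of 21 citrate cycle genes Pdhx (-0.93 ± 0.17), Dld (-0.59 ± 0.14) and Sucla2 (-0.54 ± 0.10) were lower (14 adjusted over the list alone, 12 with the block), and the list median was -0.31. Dld gave 0.17 and Sucla2 0.61 with the mean of a gene's probe sets, and a second Sucla2 probe set gave 0.65. Of 75 oxidative phosphorylation genes Uqcrfs1 (-0.45 ± 0.10) and Uqcrc2 (-0.41 ± 0.09) were lower (2 adjusted over the list alone, 19 with the block), and the median was -0.19. The camera adjusted p values of these 3 lists were 7.53e-13, 1.31e-11 and 1.22e-13, with adjusted p = 0.145, 0.145 and 0.20 with an estimated correlation. After quantile normalization the medians were -0.24, -0.15 and -0.06, the last being that of all genes. Without ventricular replicate 1 the lower genes of these lists numbered 11, 9 and 7, and without Purkinje replicate 3 or ventricular replicate 2, 3 or 4 none passed. Purkinje replicate 1 left out gave 9, 3 and 1, and Purkinje replicate 2 or 4 gave 1, 1 and 0. Within hearts 1 and 2 alone the list medians were -0.25, -0.25 and -0.06 and no gene was lower, and within hearts 3 and 4 alone they were -0.52, -0.41 and -0.35 with 24, 17 and 60 genes lower; this difference was not tested. The ratio of 3' to 5' Gapdh control signals also parted these pairs, at 1.20 to 1.29 and 1.51 to 1.72. That ratio was also higher on the Purkinje array in 4 of 4 hearts. On the same arrays the medians of the endothelial, fibroblast and smooth muscle and pericyte lists were 1.19, 1.09 and 1.28. Whether RNA quality or a lower share of myocytes lowered the metabolic lists was not tested.

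Slc16a1, a monocarboxylate transporter gene (-0.54 ± 0.11), was lower among 21 glycolysis and glucose uptake genes (7 lower adjusted over the list alone, 1 higher and 8 lower with the block, camera adjusted p = 5.49e-06, and adjusted p = 0.145 with an estimated correlation). Gbe1 (-0.85 ± 0.16), the glycogen branching enzyme gene, and Ugp2 (-0.76 ± 0.17) were lower among 20 glycogen genes (1 higher and 7 lower adjusted over the list alone, 2 higher and 10 lower with the block). For glycogen genes the camera adjusted p was 0.00507, with adjusted p = 0.145 with an estimated correlation, and 0.0815 within hearts 3 and 4. Lower glycolysis and glycogen genes numbered 4 and 5 without ventricular replicate 1, 1 and 2 without Purkinje replicate 1, and 0 and 0 without any other single array.

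Of 25 genes of autonomic receptors and signalling Rgs4 (1.39 ± 0.29), Gnai1 (1.39 ± 0.23) and Gnao1 (0.89 ± 0.21) were higher and the phosphodiesterase gene Pde3a (-0.87 ± 0.19) lower (5 and 1 adjusted over the list alone, 7 and 1 with the block). For this list camera gave an adjusted p of 0.0141, and adjusted p = 0.145 with an estimated correlation, while its median of 0.34 was -0.06 after median centring. Its higher genes numbered 0 without Purkinje replicate 3 or ventricular replicate 3, and 1 without Purkinje replicate 2 or 4 or ventricular replicate 2 or 4. Pde3a passed without Purkinje replicate 1 or ventricular replicate 1 but not without any other single array, and the smallest decrease among its 3 probe sets was -0.31. Of 10 atrial myocyte markers Stard10 (3.23 ± 0.46) and Nppa, which encodes atrial natriuretic peptide (6904 ± 3019 against 815 ± 196), were higher (5 adjusted over the list alone, 8 with the block, camera adjusted p = 1.71e-05, and adjusted p = 0.145 with an estimated correlation). Without ventricular replicate 1 there were 4 higher atrial markers. Nppa was the 1 called member among 13 stress and fetal genes (1 higher and 1 lower adjusted over the list alone, 3 and 2 with the block, camera adjusted p = 0.673).

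In the smooth muscle and pericyte list Acta2, smooth muscle actin (1853 ± 215 against 433 ± 129), Cspg4 (1.68 ± 0.21) and Kcnj8 were higher among 11 genes (9 higher and 1 lower adjusted over the list alone, also with the block). The log2 fold change of Acta2 was 2.15, and 0.80 with another probe set. Of 15 endothelial markers Cdh5 (1.87 ± 0.44), Aqp1 (1.26 ± 0.27) and Egfl7 (1.19 ± 0.28) were higher (10 adjusted over the list alone, 14 with the block). Of 16 fibroblast markers the collagen genes Col1a2 (1.17 ± 0.17) and Col3a1 (1.10 ± 0.24) were higher (11 adjusted over the list alone and with the block). For these 3 lists camera gave adjusted p values of 9.07e-05, 1.50e-06 and 7.84e-08, and adjusted p = 0.145, 0.285 and 0.145 with an estimated correlation. Without ventricular replicate 1 the higher genes numbered 6, 8 and 9, and the endothelial count was 1 without Purkinje replicate 4 and 0 without any other single array. A count of 1 fibroblast marker remained without Purkinje replicate 3 or ventricular replicate 2, 3 or 4. No macrophage marker of 9 passed (0 adjusted over the list alone, 3 with the block, among them C1qb at 1.19, adjusted p = 0.178 and 0.00123 with the block); Cx3cr1 gave 1.01. For macrophage markers the camera adjusted p was 0.0104, with adjusted p = 0.298 with an estimated correlation and 0.107 without Purkinje replicate 1.

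Cnp was higher among 6 Schwann cell and glia markers (1.59 ± 0.29; 4 adjusted over the list alone, 3 with the block, camera adjusted p = 0.00925, and adjusted p = 0.187 with an estimated correlation). Dbh, the noradrenaline synthesis enzyme gene (1.87 ± 0.41), and Uchl1 (1.79 ± 0.33) were higher among 6 autonomic neuron markers (2 higher and 1 lower adjusted over the list alone, 3 and 1 with the block, camera adjusted p = 0.180). Stat2 (1.10 ± 0.22) was higher among 9 interferon response genes (4 adjusted over the list alone, 3 with the block, camera adjusted p = 0.000487, and adjusted p = 0.187 with an estimated correlation). Another probe set of Stat2 gave only 0.11. Klf2 (1.17 ± 0.28) was higher among 26 immediate early genes that tissue dissociation can induce (1 adjusted over the list alone, 15 with the block), with 6 without ventricular replicate 1 and 0 without any other single array. Stat2 passed without Purkinje replicate 1 or ventricular replicate 1 (2 interferon genes higher there) but not without any other single array. Cnp did not pass without Purkinje replicate 2 or 3 or ventricular replicate 3 or 4, 1 neuron marker passed without Purkinje replicate 2 or 4, and neither without Purkinje replicate 3 or ventricular replicate 2, 3 or 4. For the immediate early list camera gave 0.000177, with adjusted p = 0.145 with an estimated correlation. Relative to its 8-array mean the interferon list averaged 0.62, 0.67, 0.45 and 0.18 on Purkinje replicates 1 to 4 and 0.22, -0.41, -0.56 and -1.16 on the ventricular ones (log2). The immediate early list averaged 0.49, 0.25, 0.14 and 0.31 and 0.18, -0.42, -0.58 and -0.38, and in both, as in the endothelial list, ventricular replicate 1 was the highest ventricular array.

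No gene passed, over all genes or adjusted over the list alone, among 7 endocardial, 3 adipocyte, 4 epicardial and 10 cell cycle genes (camera adjusted p = 0.804, 0.464, 0.441 and 0.253; with the block 1 lower, 1 higher, 0 and 1 higher). Their largest values were for Cytl1 (0.94) and Hand2 (-0.80; adjusted p = 0.102, 0.0146 with the block), Pparg (1.23; 0.370, 0.0349 with the block) and Retn (0.38), Krt19 (1.39) and Upk1b (0.38), and Mki67 (1.62) and Mcm6 (1.38; 0.157, 0.0269 with the block; another probe set gave -0.20). The epicardial list was called with no low value filter (0.0377). The lymphocyte list (Cd2 -0.11, Ms4a1 -0.01) and the erythrocyte list (Hba-a2 0.11) had under 3 tested genes and no test.

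**Figure D2:**
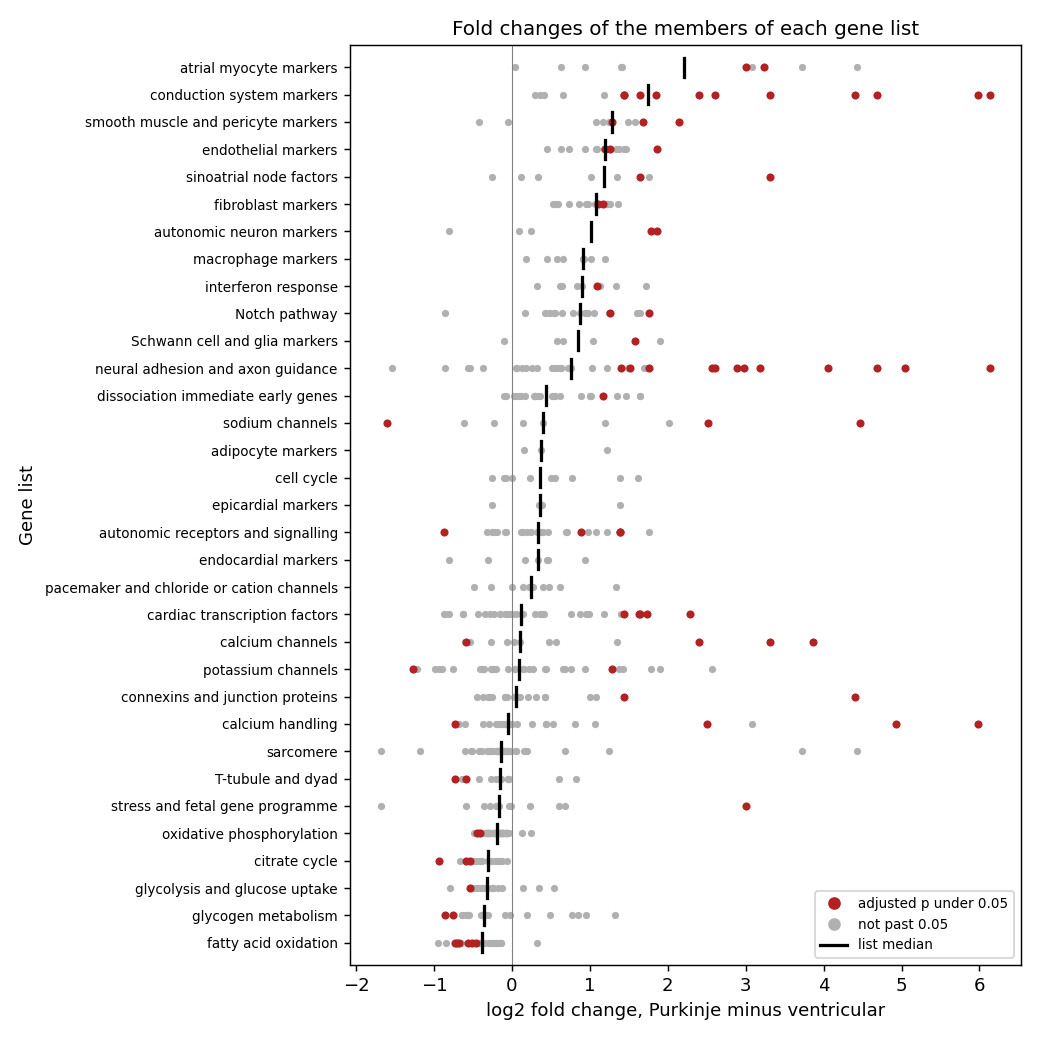
Log2 fold change, Purkinje minus ventricular, of each tested member (points; red where the adjusted p is under 0.05) of the 33 lists with at least 3 tested genes, sorted by their median (black bars). Medians ran from -0.38 for fatty acid oxidation to 2.21 for atrial myocyte markers.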

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

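The tests of whether cell types move alike, of the ratio of Sln to Myl7 and of Nppa and Stard10 were chosen only after those values were seen, and a run of the first without the endocardial list was added once its result was known. The test of array scaling for Myl7, Myl4 and Sln was also chosen then, in place of a planned test on Myl7 alone whose log2 range (9.70, and 9.95 after quantile normalization) ended under a signal of 19.9. The other splits were held to those that part all pairs after all counts were seen. Among 184 groups of 4 arrays (92 named genes in 2 groups), 8 had an array far from the others, where chance gives about 9.2. The gap of the outlying array to its nearest neighbour, as a share of the group's range on the log2 scale, was 0.903 for Cacna1h, with a signal of 95.4 on Purkinje replicate 1 and at least 328 on the other Purkinje arrays. In ventricular arrays it was 0.856 for Slit2 (43.8 on replicate 2), 0.933 for Cacna2d2 (84.0 on replicate 4), 0.838 for Gbe1 (410 on replicate 1), 0.939 for Stard10 (61.4 on replicate 1), 0.870 for Col3a1 (235 on replicate 4), 0.929 for Aqp1 (805 on replicate 1) and 0.878 for Cspg4 (83.2 on replicate 3).

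The median log2 fold change of 42 endothelial, fibroblast and mural markers was 1.17, and 3, 2 and 3 of them passed. Array scaling and the low end of the signal range are argued against: this median lay at percentile 100 of 10000 random lists matched on mean signal, whose highest median was 0.35. A lower share of myocytes, with every other cell type carried over alike, would need equal shifts. The medians differed by 0.94 (95% interval of a bootstrap over genes 0.62 to 1.797) between the mural list, at 1.28 (1.08 to 1.58), and the endocardial list, at 0.34 (-0.31 to 0.46). These were picked as the highest and lowest of 7 lists, a choice that the interval does not allow for. The difference rests on the endocardial list, whose 7 genes include Hand2 at 275 on the ventricular arrays. Among the other 6 lists the largest difference was 0.43 (-0.46 to 1.04). A lower share of myocytes therefore stays open. More endothelial, fibroblast and mural cells on the Purkinje arrays, or expression in Purkinje cells, stay open and were not tested, since cell type and group coincide, although a sort on both reporters would remove non-myocytes. Of these genes, 5 mural and 1 endothelial marker belong to another list too, and abundant members were Rgs5 (3672 against 1840) and Fabp4 (5444 against 3653).

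Myl7, Myl4 and Sln differed between hearts in the Purkinje arrays: Myl7 signals were 1740, 3920, 377 and 4.70 in hearts 1 to 4, and 282 on ventricular replicate 2 against at most 21.7 on the other ventricular arrays. Over the Purkinje arrays with signals above 19.9 (3 for Myl7 and Sln, 4 for Myl4) the log2 ranges of Myl7, Myl4 and Sln were 3.38, 3.71 and 4.37. After quantile normalization they were 3.39, 3.73 and 4.69, at least 1.004 times as wide. The arrays already shared a trimmed mean, so quantile normalization could hardly have narrowed these ranges, and that result decides little. Array scaling of that size is argued against by the medians of the 4 Purkinje arrays, which lay between 36.1 and 42.9. Atrial myocytes among the sorted cells remain possible: the ratio of Sln to Myl7 moved by 2.04-fold over the 4 arrays with Myl7 above 100, and among the Purkinje arrays 5 of 7 other atrial markers were highest on replicate 2 (Kcnj3, 1 of them, was higher still on ventricular replicate 2, 1150 against 1032), but a sort on the Cntn2 reporter would remove atrial myocytes that lack it, and joint regulation in Purkinje cells would give the same. Atrial cells as the whole source of Nppa and Stard10 are argued against, since both were higher, on average by 1.49 (log2) on the Purkinje arrays of hearts 3 and 4, where Myl7 was lower, than on those of hearts 1 and 2. With cell type in the limma fit, over all 8 arrays, Myl7 (adjusted p = 0.000749) and Myl4 (0.00282) differed between hearts. Sln did not pass there (0.0506). These genes were picked after their values were seen, and why the hearts differed was not tested.

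Purkinje replicate 1 lay nearer the ventricular arrays: on a scale where the ventricular mean is 0 and that of the other 3 Purkinje arrays is 1, its median place was 0.20 for 88 genes higher in Purkinje cells, against 0.82 to 1.54 for the other Purkinje arrays. Each of those was placed by its own genes (44, 21 and 42 for replicates 2, 3 and 4), on a scale whose mean includes replicate 1. Ventricular myocytes among the sorted cells of replicate 1 would place genes higher and lower in Purkinje alike if signals are linear. The 69 lower genes were at 0.46, a difference of -0.26 (95% interval of a bootstrap over genes -0.37 to -0.14). The higher genes were picked at a larger fold-change cutoff than the lower ones. On Purkinje replicates 2, 3 and 4 higher genes were at 0.82, 1.54 and 1.45, and lower genes at 0.76, 0.86 (1 gene) and 1.25. The difference rests on 1 array and unlike cutoffs, so ventricular myocytes stay open. The place of the higher genes on replicate 1 was 0.18 (0.13 to 0.23) after quantile normalization. With a trimmed mean shared by all arrays that step could hardly have moved it. Array scaling of that size is argued against by the median signal of replicate 1, 36.1 against at most 42.9 on the other Purkinje arrays. A lower expression of conduction genes in the cells sorted from heart 1 stays open and was not tested.

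The arrays are paired by heart, and 8 splits into 4 and 4 part all 4 pairs, too few for a share under 0.05. Among these the real one gave 365 genes and the highest other 0, and with the heart as a block 2108 and 0. For lists called by camera the real one gave 20 and the highest other 16. The split with 16 kept Purkinje replicates 1, 2 and 3 on 1 side, so it held part of the real contrast. Those of the 8 with 2 arrays of each cell type per side gave up to 5 lists. Splits that do not part all 4 pairs differ in mixing hearts. Of all 35 splits 1, the real one, gave as many as 365 genes (highest other 263), 239 higher genes (162), 235 genes at least 2-fold apart (157) and 20 lists (19). For the 126 lower genes 3 splits gave as many in either direction (highest other 162). The split with 263 genes parts hearts 1 and 2 from hearts 3 and 4, a structure of the samples, and gave 4 lists. Camera at its preset correlation called up to 17 lists on the 32 splits where no gene passed. The split with 17 also kept Purkinje replicates 1, 2 and 3 on 1 side. On splits with 2 arrays of each cell type per side the highest was 9 lists.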

How the results depend on the processing

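The settings with a floor of 32, the pair of hearts, the added blocks, Cntn2 left out and the authors' paired test were chosen after seeing the data. Counts of differing genes moved most (total, higher, lower, at least 2-fold): 365, 239, 126 and 235 became 2108, 1187, 921 and 810 with the heart as a block, and 162, 122, 40 and 124 after quantile normalization. Median centring gave 2607, 2385 lower and 614 at least 2-fold, no variance trend 126, 117, 9 and 119, and array weights 937, 579, 358 and 542. No filter gave 73 lower genes, every probe set 380 higher and 380 at least 2-fold, and 64 added 126 at least 2-fold. The pair of hearts as a term gave 1845, 1009, 836 and 746, hearts 1 and 2 alone 3, 3, 0 and 3, and hearts 3 and 4 alone 1579, 766, 813 and 780. The block with the floor of 32 gave 2174, 1219, 955 and 664, with quantile normalization 1534, 827, 707 and 574, and without heart 1 2415, 1334, 1081 and 1069. An unequal-variance test per gene and the authors' deposited paired test each gave 0, 0, 0 and 0 after adjustment, with 2044 and 2617 genes at an unadjusted p under 0.05 (limma: 2711). Leaving out an array or a heart gave totals from 6 to 957, higher from 6 to 647, lower from 0 to 310 and at least 2-fold from 6 to 614. The number of lists called by camera stayed between 16 and 22 in every setting run (20 in the comparison as planned). With Cntn2 left out 363, 238, 125 and 234 genes passed. Of 68 called named genes, 17 stayed called without each array in turn (in fits without the block), 34 after quantile normalization and 68 with the block, which changed no other call than those given beside results. Dld (0.17) and Sucla2 (0.61) turned positive with the mean of a gene's probe sets, and the sarcomere list turned direction (median -0.0457, adjusted p = 0.942) after quantile normalization, with the block too (0.897). Lists that gained or lost their camera call had these medians. After quantile normalization, without and with the block, they were connexins 0.14, T-tubule -0.0729 and transcription factors 0.0598. Within hearts 1 and 2 they were sarcomere -0.0257 and autonomic receptors 0.23, and within hearts 3 and 4 sinoatrial 0.42, glycogen -0.25, macrophage 0.73 and Schwann cell 0.98. Median centring gave sodium channels -0.00101 and autonomic neuron 0.61, every probe set sodium channels 0.60, the mean of probe sets autonomic receptors 0.34, and no filter autonomic neuron 0.50 and epicardial 1.04. Leaving out an array or a heart gave sinoatrial medians from 0.84 to 1.40 and macrophage medians from 0.57 to 1.03. Except in settings with fewer arrays or genes, the cause was not tested. The files gave no detection calls to filter on, and the annotated table equals the value table, so neither alternative was run. Signals near 19.9 limit folds of the lowest genes.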

Other observations

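Several genes, chosen after their values were seen, differed between hearts and little between the cell types of a heart. Dbp, a transcription factor gene under clock control, had signals of 374, 1133, 277 and 548 in Purkinje replicates 1 to 4 and 388, 1193, 246 and 482 in the ventricular ones. Its hearts spanned 4.46-fold, while the cell types of a heart were within 1.14-fold. Of 7 other clock genes Hlf passed between hearts (limma adjusted p = 0.0411, up to 5.48-fold apart within a heart), and Per3, Nr1d1, Nr1d2, Tef, Ciart and Cry1 did not (0.0505 to 0.173). Zbtb16 spanned 2.97-fold between hearts and at most 1.27-fold within one, and the metallothionein gene Mt2 6.59-fold and 1.25-fold. With cell type in the limma fit, 930 genes differed between hearts.

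The Iroquois genes form 2 clusters in the GRCm38.p6 annotation; Irx4 and Irx6 were chosen after their values were seen. Irx1 (log2 fold change 1.74) and Irx2 (2.28) were higher in Purkinje cells and their neighbour Irx4 gave -0.44 ± 0.31 (adjusted p = 0.435). In the other cluster Irx5 (1.63) was higher, while Irx3 gave 0.36 and Irx6 0.05; after median centring Irx3 was at -0.04 and Irx6 at -0.35, and after quantile normalization Irx6 was at -0.35. The difference between neighbours was not tested.

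Over both cell types together, with group in the limma fit, 619 genes were higher and 967 lower in hearts 3 and 4 than in hearts 1 and 2. Each side held 2 hearts with 2 arrays each, and the arrays of a heart are no independent replicates of it. The pairs of hearts were chosen after seeing the data, and this difference was not tested within either cell type. The ratio of 3' to 5' Gapdh control signals was 1.20 to 1.29 in hearts 1 and 2 and 1.51 to 1.72 in hearts 3 and 4. The ratios of transferrin receptor (0.351 to 0.421 and 0.508 to 0.637) and 18S rRNA (0.991 to 1.11 and 1.18 to 1.25) also parted these hearts, while that of actin overlapped (0.672 to 0.818 and 0.706 to 0.785). Within hearts the Gapdh ratio was higher on the Purkinje array in 4 of 4 (1.24 against 1.23, 1.28 against 1.20, 1.64 against 1.51 and 1.72 against 1.51), so this sign of RNA quality ran with cell type. The transferrin receptor ratio was higher on it in 3, that of 18S rRNA in 2 and that of actin in 1 of 4 hearts.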
